A study of Mus musculus with 4 samples.

How the data were processed

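Hearts of Abro1 knockout mice and wild-type mice on a C57BL/6 background were profiled by methylated RNA immunoprecipitation sequencing (MeRIP-seq), in which RNA fragments are pulled down with an antibody against N6-methyladenosine (m6A) and sequenced beside an input library made without the pull-down. There were 4 libraries, 1 input and 1 m6A immunoprecipitate per genotype. The labels do not say how many animals went into a library, and there were no replicates, so no test between the genotypes was made and no spread between animals is known. Per the labels' protocols, RNA was extracted with Trizol, enriched with a GenSeq kit and sequenced as paired-end reads of 150 bases. The labels' extraction protocol names a directional NEBNext kit for the libraries, whereas the series' design text names a stranded KAPA kit, so the kit is uncertain. Both keep the strand.

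Per the submitters' processing notes, cutadapt 1.9.3 and HISAT2 2.0.4 were used with the mm10 genome. Per the deposited tables, the site names begin with MACS, the name of a peak caller. Its version and settings are not given in the sources used here. Per the series' design text, each deposited table was made from the input and the immunoprecipitate of one genotype together, so sites were called once per genotype and the tables hold no value per library. Each genotype has 1 list of sites in mRNAs, with an interval, a strand, one transcript and one gene symbol per site. The site numbers ran in genome order on each chromosome and reached 55550 in the wild-type list of 10814 sites and 50266 in the knockout list of 10388 sites. The lists used here thus hold 19.5% and 20.7% of the numbers up to the highest one. The filter behind this is not given beyond the word mRNA in the deposited tables.

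The deposited fold enrichment is a linear ratio of immunoprecipitate over input per site, as the authors' peak caller gave it. Per the file headers, the deposited score is minus 10 times the log10 of the peak caller's p, so a larger score is a smaller p. It ran from 50.0 to 3233, and 911 wild-type and 872 knockout sites stood at exactly 3100, so strong sites are only partly ranked by it. The deposited false discovery rate is in percent, as the authors' peak caller gave it. It was 100% for 10385 of the 10388 knockout sites (99.97%) and for 8960 of the 10814 wild-type sites (82.9%), with minima of 40.0% and 80.6%. Fold, score and false discovery rate belong to the site in its own list; they were used to describe, rank and filter sites within a list. The lists give no read counts, so the sequencing depth is unknown and no limit of detection could be set. Shares of sites are given with exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only.

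Sites of the 2 lists were compared with bedtools 2.31.1, counting an overlap of at least 1 bp on the same strand, and with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. Genes were compared by symbol: a gene was in both lists, in the wild-type list only or in the knockout list only. A gene listed in one list only is a gene with no site in the other list as used here, which does not show that its RNA was unmethylated. Of 6660 symbols in either list, 6568 were matched to a gene of a RefSeq table for GRCm38.p6 (the same assembly as mm10) through the gene ID that the lists give or, where they give none, a current or older symbol. Genes were placed with that table, which gives gene spans but no exons or untranslated regions; whether a site is exonic, coding or in an untranslated region was therefore not determined. Of the 10724 wild-type and 10295 knockout sites with a matched gene, 99.0% and 98.9% had their midpoint inside the span of their gene, and these were sorted into 5 equal parts of the span from the 5′ to the 3′ end. The planned positions relative to the stop codon and the planned search for the DRACH motif need a transcript annotation and a genome sequence and were not run. Coordinates are 1-based.

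The comparisons of the report, the gene lists, the rule for named genes and the alternatives not named below as added were fixed before the data were examined. The rule names Abraxas2; the 10 genes per list with the smallest p among genes with a site in one list only; the 5 sites per list with the largest fold among genes in both; and up to 4 members of each gene list, first those in one list only by p, then those in both by the largest wild-type fold. A gene in one list only is given with its strongest site by score, and a gene in both with its largest wild-type fold and the knockout site that overlaps it. Choosing the site by its wild-type fold tends to make the knockout fold look lower, so these pairs do not compare the genotypes. Mcm3, Meis1, E2f2, Ltbp3, Smad9, Id4, Dusp1 and Maff, which complete counts of 5 or fewer, the genes listed without a site, AK158854, and the neighbours and overlapping genes of named sites were named after the values were seen. A few genes that the rule or a count would name are not reported here. For each of 29 gene lists, the number of members with a site in one list only was set against 10000 random sets of as many genes with a site in either list. Without transcript lengths these sets were not matched on length; sets matched on the largest score of the genes, and counts with both directions added together, were added after the data were seen. The overlap steps returned the planted number in 5 of 5 settings on 10388 simulated sites. Alternatives changed the overlap rule, strand, thresholds, list length and the matching of genes; genes matched by gene ID, genes with no site of the other list within 2 kb, gene spans of at least 20 kb and positions of sites with and without an overlapping site were added after the data were seen.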

Results

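The study compared the m6A methylomes of hearts from mice lacking Abro1 and from wild-type mice. Abro1, now named Abraxas2, is the scaffold of a cytoplasmic deubiquitinase complex, and m6A is the most common internal modification of mRNA. The data were 1 list of m6A sites per genotype, each called from 1 immunoprecipitate against 1 input library, without replicates. The wild-type list held 10814 sites in 5888 genes and the knockout list 10388 sites in 5727 genes. Sequencing depth is unknown from these lists. All differences below are between those lists, not between groups of animals. Coordinates are in mm10.

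The first comparison concerned the targeted gene. No site was assigned to Abraxas2 in either list. However, the knockout list held a site on chromosome 7 from 132859235 to 132859890 on the plus strand, which began 10 bp into the annotated span of Abraxas2 (132859225 to 132885114). This 656 bp site was assigned to the transcript AK158854, with a fold enrichment of 8.29 and a score of 121. The wild-type list held no site inside the Abraxas2 span. The nearest site upstream lay in Mettl10 from 132852499 to 132852673 in both lists, with a fold of 9.66 in the wild-type list and 4.45 in the knockout list. The part of the gene that was removed is not given in the labels, so the sites neither check nor contradict the genotype.

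**Figure D1:**
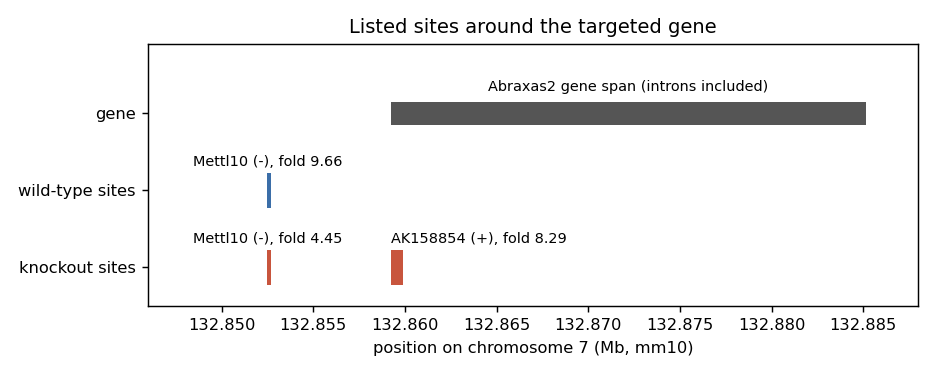
Sites listed around Abraxas2 on chromosome 7 (position in Mb, mm10), drawn to scale for the wild-type list (blue) and the knockout list (red) with strand and fold enrichment, below the span of the gene (grey). The knockout list alone has a site inside the span, at its left end, with a fold of 8.29.

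The 2 lists had similar outlines. The site with the largest fold was in Gm4076 in both lists (chromosome 13, 85126999 to 85127514, minus strand), at 1286 in the wild-type list and 1099 in the knockout list. Among genes with a site in both lists, the next wild-type sites lay in Mphosph8 (367) and Gm4799 (239). Then came Rrbp1, a ribosome-binding protein of the endoplasmic reticulum (234), and Tia1, an RNA-binding protein of stress granules (206). Saxo1, in the wild-type list only, had a larger fold than these, 872. Among genes in both lists, the next knockout sites lay in Gm4799 (271), Tia1 (269), 0610011F06Rik (203) and the transcription elongation factor Supt5 (182). Each of these knockout sites overlapped a site of the same gene in the wild-type list, with folds of 239, 206, 130 and 134. The Rrbp1 site overlapped a knockout site with a fold of 177, whereas the Mphosph8 site (chromosome 14, 56693485 to 56693578) overlapped none. The median fold was 9.35 (quartiles 6.69 and 14.5) in the wild-type list and 7.96 (5.61 and 12.2) in the knockout list, with median scores of 266 and 270. Because each list was called on its own, these medians describe the lists and do not measure a change in methylation.

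Sites were most frequent at the ends of genes in both genotypes. In the wild-type list, 35.7% of sites (95% interval 34.8 to 36.6) lay in the last 20% of the gene span and 25.5% (24.7 to 26.3) in the first 20%. In the knockout list these shares were 34.8% (33.9 to 35.7) and 26.1% (25.3 to 27.0), and the intervals of the lists overlapped for both parts. Sites without an overlapping site in the other list were chosen after the data were seen. Of these, 37.6% (35.7 to 39.6) of wild-type and 33.3% (31.3 to 35.5) of knockout sites lay in the last 20%. The intervals for this part did not overlap. The first 20% held 604 of 2420 such wild-type sites (interval 23.2% to 26.7%) and 566 of 1986 such knockout sites (26.5% to 30.5%). The intervals for that part overlapped. All these intervals cover counting error only and treat sites as independent, although many genes carried several sites. Without replicates, they do not test a difference between the genotypes. An even spread over the span would put 20% in each part. Exons were not placed, so 20% is not the share to expect for sites in mRNAs. The second part held the fewest sites, 1089 in the wild-type list and 1019 in the knockout list. Spans include introns, so these shares are not positions in mature transcripts.

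The next comparison asked how far the lists overlapped. Of the wild-type sites, 8350 (77.2%, interval 76.4 to 78.0) overlapped a knockout site, and 8351 of the knockout sites (80.4%, 79.6 to 81.2) overlapped a wild-type site. There were 5904 sites with identical start and end in both lists, all with the same gene symbol. Their median fold was 10.3 in the wild-type list (quartiles 7.19 and 16.8) and 8.76 in the knockout list (6.02 and 13.9). Their median scores, 414 and 421, went the other way, and neither value measures a change in methylation. Some site edges lay exactly at the edge of the annotated gene in both lists, such as 61085067 for Pdgfrb and 87446935 for Calm2. Whether intervals were cut at annotated edges is not given, so identical ends may partly come from the annotation. The overlap depended on the strength of the site. In the weakest 10% of each list by score, 58.2% of wild-type sites (55.2 to 61.1) and 55.1% of knockout sites (52.0 to 58.2) had no overlapping site in the other list. In the strongest 10%, these shares were 2.40% (1.58 to 3.50) and 1.64% (0.956 to 2.61). The shares of 77.2% and 80.4% differ through the lengths of the lists, since nearly the same number of sites overlapped in each.

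**Figure D2:**
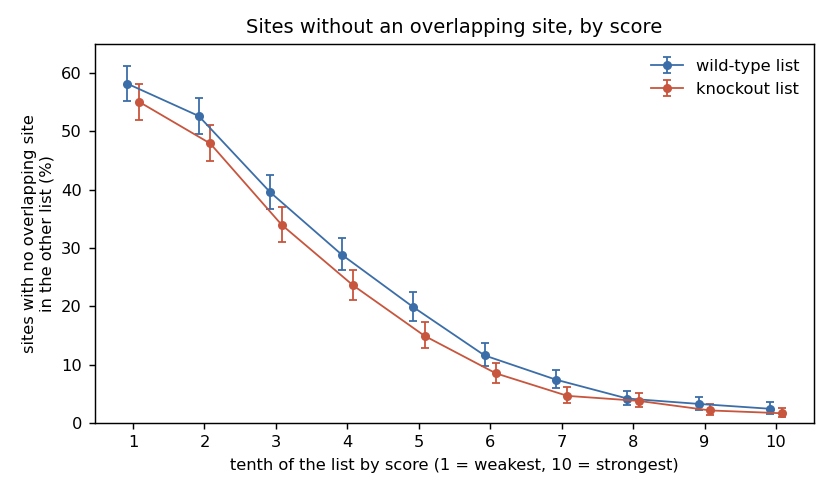
Percent of sites with no overlapping site in the other list (vertical axis) by 10% steps of the list's own score (horizontal axis, weakest to strongest), with exact 95% binomial intervals, for the wild-type list (blue) and the knockout list (red). The share falls at every step, from 58.2% to 2.40% in the wild-type list and from 55.1% to 1.64% in the knockout list.

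Most genes carried sites in both genotypes. There were 4955 genes in both lists, 933 in the wild-type list only and 772 in the knockout list only. Genes in one list only had weak sites, with median scores of 97.9 (wild type) and 93.1 (knockout) for their strongest site, against 510 and 474 for the genes in both lists. Of the genes in one list only, 842 (wild type) and 716 (knockout) had 1 site. The 4955 genes in both lists held 9781 wild-type and 9555 knockout sites. Part of the gap in scores can thus come from taking the strongest of more sites. The difference between 933 and 772 is that between the gene totals of the lists and depends on how many sites each holds, with 850 and 858 genes at equal length. Among the genes in both lists, 3448 (69.6%) had the same number of sites in each.

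The 10 strongest genes in the wild-type list only included Tpm1, Uqcrh and Hnrnpk. Tpm1, the alpha-tropomyosin of the thin filament, had a site on chromosome 9 from 67035995 to 67036128 with a fold of 13.5. Uqcrh, a subunit of respiratory complex III, had a fold of 7.39 (chromosome 4, 116074916 to 116075071), and the RNA-binding protein Hnrnpk one of 19.0 (chromosome 13, 58399893 to 58399990). Each of the 3 sites had a score of 3100. The small GTPase Hras (fold 14.5, score 2912), the co-chaperone Bag1 (13.6 and 2629) and Kitl, the ligand of the Kit receptor (13.7 and 2576), also belonged to it. Saxo1, a microtubule-associated protein, had the largest fold, 872 (chromosome 4, 86478873 to 86479026). The splicing factor Prpf38b (94.2) and Plekha4 (93.0) completed the group with Gm1078 (80.9), which the RefSeq table treats as the gene Sbk3. The deposited false discovery rates of these 10 sites were high, from 83.3% to 87.7%.

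The 10 strongest genes in the knockout list only were Atg4a, March2, Sbk3, Snx32, Rbm39, Stk16, Atp5g3, Tesk1, Cxx1a and Eef2kmt. Atg4a, a protease that processes ATG8 proteins in autophagy, had a site on the X chromosome from 140995563 to 140995641 with a fold of 30.4 and a score of 3151. The sorting nexin Snx32 (fold 26.6), the splicing factor Rbm39 (23.4), the kinase Stk16 (18.6) and Atp5g3, a c-ring subunit of ATP synthase (15.6), each had a score of 3100. The kinase Tesk1 had a fold of 17.5 and Cxx1a one of 5.32. Of the remaining members, March2 (61.0) and Eef2kmt (30.1) overlapped wild-type sites assigned to Hnrnpm (88.1) and Fam86 (36.6). Sbk3 (59.6) lay 488 bp from the wild-type site of Gm1078, which carries the same gene ID. For these 3 genes the other list thus held a site at the same place or under the same gene ID. All 10 sites had a deposited false discovery rate of 100%, as nearly all knockout sites had.

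Of 11 writer genes, 7 had a site in both lists, 1 in the wild-type list only and 0 in the knockout list only. Zc3h13, a scaffold of the writer complex, had 12 wild-type and 11 knockout sites; its largest wild-type fold was 139 and the overlapping knockout site had 125. The list symbol 1110037F02Rik, the writer subunit Virma, had overlapping sites with folds of 42.4 and 44.9, and Rbm15b had 18.7 and 13.6. Mettl16, a methyltransferase of U6 snRNA, had a weak site in the wild-type list only (fold 8.69, score 80.2). Mettl3, the catalytic subunit, had no site in either list, nor had Mettl5 and Pcif1. Of 15 erasers and readers, 7 had no site and 7 were in both lists, among them the nuclear reader Ythdc1 (folds 59.6 and 44.0), Fmr1 (53.4 and 35.8) and Ythdf3 (17.5 and 9.24). The demethylase Alkbh5 had a site in the wild-type list only (fold 7.86, score 178).

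Of 11 genes of the Abro1 complexes and partners, 2 were in both lists. Uimc1, which recruits the related nuclear complex to ubiquitin, had overlapping sites with folds of 42.3 and 28.5, and Babam1, a shared subunit, had 4 wild-type and 2 knockout sites. The largest wild-type fold of Babam1 (4.93) was at a site without an overlapping knockout site. Bard1, the partner of BRCA1, had a weak site in the wild-type list only (fold 8.99, score 52.9). Of 14 serine and one-carbon genes, 2 had a site, each in both lists. Psph had none. This list was chosen with prior knowledge of the study and is not independent of it.

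Of 31 calcium-handling and channel genes, 17 were in both lists, 0 in the wild-type list only and 1 in the knockout list only. Trdn, the junctional protein triadin, had 23 wild-type and 22 knockout sites, with a largest wild-type fold of 146 and an overlapping knockout fold of 89.1. Another of its knockout sites had a fold of 182. Calm2 (43.9 and 38.0) and the calcium-binding protein Hrc (42.5 and 25.8) were also in both, whereas Jph2, the junctophilin that couples membranes in the dyad, had 2 sites in the knockout list only (fold 7.4, score 854). Of 30 sarcomere genes, 13 were in both lists. Besides Tpm1, the Z-disc gene Ldb3 was in the wild-type list only (fold 6.82, score 79.7), and Myom1 of the M-band (5.29 and 145) and the filamin Flnc (4.34 and 61.8) in the knockout list only. Of 28 cardiac transcription factors, 21 were in both lists. Gata4 (fold 4.35, score 93.3) and Nfatc3 (6.52 and 51.3) were in the wild-type list only, and Gata6 (5.41 and 117) and Mef2d (3.04 and 99.0) in the knockout list only. Of 21 stress and hypertrophy genes, 5 were in both, including Ankrd1 (21.1 and 20.7), Mlip (17.3 and 9.73) and Atf3 (9.26 and 7.08), and 1 was in the knockout list only.

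Several cell cycle genes were in one list only. Of 40 members, 13 had a site, of which 6 were in both lists, 5 in the wild-type list only and 2 in the knockout list only. Those 5 were the cyclin Ccna2 (fold 6.82, score 233), the phosphatase Cdc25a (9.28 and 84.4), the replication helicase subunit Mcm3 (8.69 and 79.5), Meis1 (5.69 and 70.1) and E2f2 (7.19 and 59.7). The 2 were Myc (5.42 and 207) and E2f3 (5.96 and 108). As many wild-type-only members occurred in 2.66% of 10000 random gene sets and in 5.14% of sets matched on score. Of the 58 counts compared with random sets, this was the only one reached by 5% of sets or fewer, and none was with the matched sets. With both directions added together, as a further 29 counts chosen after the data were seen, the 7 cell cycle genes were reached by 2.91% of sets (5.37% matched) and the 2 erythroid genes by 7.11% (1.76% matched).

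Most signalling genes with a site were in both lists. Of 33 Wnt and Notch genes, 25 were in both lists, with Jag2 at folds of 28.2 and 21.4. The receptors Notch3 (fold 14.0, score 1521), Fzd4 (11.3 and 234) and Notch4 (7.48 and 116) were in the wild-type list only, and 0 were in the knockout list only. Of 34 TGF-beta and BMP genes, 19 were in both, 5 in the wild-type list only, Acvr1 (5.76 and 135), Acvr2b (4.62 and 78.5), Smad2 (4.85 and 77.5), Ltbp3 (5.25 and 71.9) and Smad9 (8.39 and 61.4), and 2 in the knockout list only, Tgfb1 (7.05 and 162) and Id4 (5.40 and 51.9). Of 23 Hippo genes, 11 were in both; Cyr61 (5.23 and 90.2) and Tead3 (8.37 and 87.6) were in the wild-type list only, Tead4 (5.61 and 109) and Wwtr1 (3.39 and 56.5) in the knockout list only. Of 40 ubiquitin and deubiquitinase genes, 25 were in both, Otud4 in the wild-type list only (9.66 and 1774), and Stambp (7.84 and 199), Usp28 (7.65 and 161) and Uchl1 (6.67 and 61.3) in the knockout list only. Of 28 p53 and DNA damage genes, 13 were in both, with Rad50, a subunit of the break-sensing complex, at 46.2 and 19.0. H2afx (12.3 and 336) and Rnf8 (5.61 and 56.4) were in the wild-type list only, and the pro-apoptotic gene Bax in the knockout list only (8.74 and 604).

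Of 34 innate immune and interferon genes, 8 were in both lists. The adaptor Traf6 (fold 13.5, score 1647) and Socs1 (12.4 and 257) were in the wild-type list only, and 3 genes, among them Nfkbia (11.1 and 344) and Socs3 (6.29 and 262), in the knockout list only. Of 30 immediate early genes, 19 were in both, 3 in the wild-type list only, Mcl1 (4.72 and 604), Fos (4.71 and 92.2) and Dusp1 (9.54 and 52.0), and 3 in the knockout list only, Zfp36l2 (4.25 and 685), Maff (5.87 and 51.2) and Fosb (6.4 and 54.7). Of 19 clock genes, 10 had a site, each in both lists, among them Rora (25.2 and 22.1), Bhlhe40 (20.8 and 17.5) and Tef (15.2 and 12.5). Nfil3 had its largest wild-type fold (11.4) at a site without an overlapping knockout site.

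Of 29 oxidative phosphorylation and TCA cycle genes, 4 had a site. Of these, 3 were in both lists, including Idh2 (folds 16.1 and 15.4) and Suclg1 (11.2 and 7.38), and Cox5a was in the knockout list only (fold 8.0, score 85.3). Of 32 fatty acid genes, 11 were in both. Ppara, a transcription factor that drives fatty acid oxidation, was in the wild-type list only (23.8 and 799), as was Mlycd (3.74 and 66.7), and Acacb (4.71 and 88.4) and Esrrg (3.91 and 58.0) were in the knockout list only. Of 30 glucose and insulin genes, 19 were in both, Hk2 (3.02 and 150), Pfkfb2 (7.60 and 127) and Igf1 (6.75 and 71.0) in the wild-type list only and Prkag2 (4.93 and 60.4) in the knockout list only. Of 25 autophagy and mitochondrial quality genes, 5 were in both, including Tfeb (16.4 and 8.11) and Ulk2 (14.1 and 9.73), and Atg16l1 (6.65 and 126) and Atg5 (8.25 and 81.0) were in the wild-type list only.

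Of 32 fibroblast and matrix genes, 20 had a site and 17 were in both, including Pdgfrb (folds 30.1 and 27.8). Col3a1 (fold 8.35, score 269) and Tcf21 (10.6 and 106) were in the wild-type list only, and Lox in the knockout list only (8.80 and 72.6). Of 27 endothelial genes, 18 had a site and 16 were in both, including Klf4 (22.2 and 17.6) and Cdh5 (21.9 and 18.4), and Flt1 (11.3 and 218) and Ptprb (4.14 and 145) were in the knockout list only. Of 15 smooth muscle and pericyte genes, 9 had a site and 7 were in both, including Lmod1 (98.3 and 74.4) and Myh11 (31.2 and 24.2), with Notch3 in the wild-type list only and Smtn in the knockout list only (9.32 and 247). Of 19 atrial and conduction genes, 14 had a site and 12 were in both, including Nr2f2 (43.4 and 32.9) and Bmp10 (26.6 and 20.2), and Dkk3 (5.96 and 105) and Cacna1d (8.99 and 79.9) were in the wild-type list only. Of 28 leukocyte genes, 6 had a site and 5 were in both, including Cx3cr1 (16.2 and 6.01), Itgam (14.6 and 10.2) and Cd163, whose largest wild-type fold (14.4) was at a site without an overlapping knockout site, and C1qa was in the knockout list only (5.75 and 149). Of 15 adipocyte genes, 4 had a site, of which Prdm16 (21.3 and 18.3) and Pparg (8.67 and 5.71) were in both, and Lipe (7.10 and 73.8) and Adipoq (3.60 and 52.0) were in the knockout list only. Of 20 genes of skeletal muscle and other neighbouring tissues, 3 had a site and 2 were in both, including Acta1 (folds 3.74 and 3.92), and the creatine kinase Ckm was in the knockout list only (3.31 and 329). Of 9 erythroid and blood genes, 2 had a site, of which Slc4a1 was in the wild-type list only (14.4 and 225) and Alas2 in the knockout list only (11.01 and 215).

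**Figure D3:**
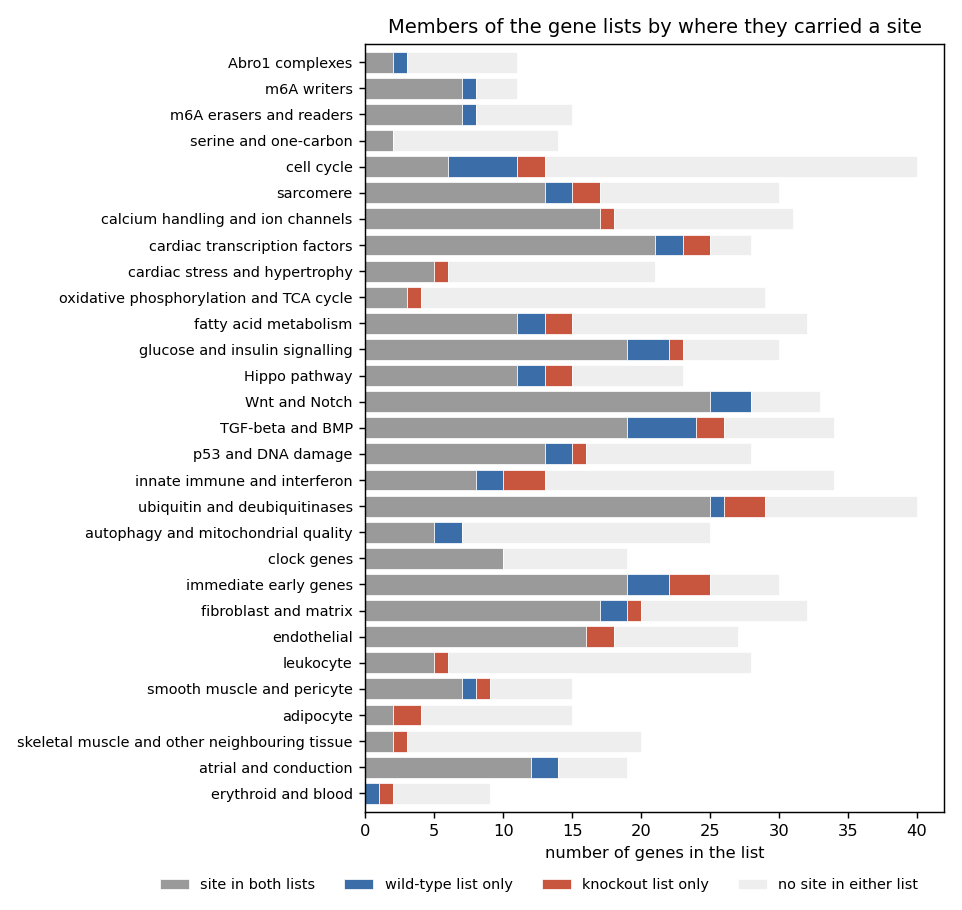
Number of genes (horizontal axis) in each of the 29 gene lists that carried a site in both lists (grey), in the wild-type list only (blue), in the knockout list only (red) or in neither (light). Over all lists, 293 of 370 genes with a site were in both, 42 in the wild-type list only and 35 in the knockout list only.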

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

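Matching by gene ID, the 2 kb rule, gene spans of at least 20 kb and the split of positions by overlap were chosen after the data were seen. The lists hold no read counts, so depth limits each absence by an unknown amount. The overlap of sites was 76.0% of the wild-type and 79.1% of the knockout list with a reciprocal overlap of 50%, 70.0% and 72.8% with midpoints within 100 bp, 97.0% and 97.8% for the strongest 25% of each list, and 78.8% and 78.8% for lists of equal length, which makes the shares alike by construction. At a fold of at least 4 it was 82.1% of the knockout list; the wild-type share at that fold, and both shares with strand ignored, moved by less than their intervals. Requiring a site in the strongest 25%, with absence judged on the full other list, left 2103 genes in both, 30 in the wild-type list only and 21 in the knockout list only, because fewer sites count as present. The members of the gene lists in one list only, summed over the lists, then numbered 5 (wild type) and 1 (knockout), against 43 and 35 without this requirement. These sums count Notch3 in both the Wnt and Notch list and the smooth muscle and pericyte list. The counts of genes in each class stayed within 1.5 times under the other alternatives, with 926 and 766 when matched by gene ID, 931 and 768 by overlap of sites, and 926 and 761 with no site of the other list within 2 kb. The overlap and 2 kb settings can only lower the counts of genes in one list only. By overlap of sites, 4829 genes had a site that overlapped the other list, against 4955 genes in both lists. With lists of equal length the genes in one list only numbered 850 and 858, and that setting by itself brings the counts together. Of 100 named genes in one list only, 97 stayed so with lists of equal length, 93 at a fold of at least 4 and 28 in the strongest 25%. The others, 3, 7 and 72, had no site left in these settings, and 0 came to be in both lists. By overlap of sites 2 of the 100 counted as in both lists, and by gene ID 3 did. The share of sites in the last 20% of the gene span was 33.9% (wild type) and 33.4% (knockout) from the start of the site, 38.0% and 37.1% from its end, and 37.4% and 36.5% in genes spanning at least 20 kb; it was 36.9% in the strongest 25% of the wild-type list, and 37.6% and 33.3% for sites without an overlapping site. In each of these settings it exceeded 20%, the share under an even spread over the span, which takes no account of exons. Apart from the settings that keep fewer sites, the cause of these shifts was not tested. Positions near the stop codon and the DRACH and GGAC motifs, with their alternatives, were not run, since no transcript annotation or genome sequence was used here. No paired analysis was possible because each genotype had 1 list. No replicate could be left out for the same reason.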

Other observations

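The tests on gene assignment, on missing site numbers and on remaining Abraxas2 RNA were chosen after the result was seen. A bound of under 10%, first set for the test of gene assignment over all strong genes, was not met, and another bound, an interval below 50%, replaced it. The fall of unshared sites with score was set before its percentages were seen, but after the low median scores of genes in one list only were known.

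The genes with the most sites over both lists, named after their values were seen, included several for large structural proteins. Trdn had 23 wild-type and 22 knockout sites, Ktn1 19 and 20, the myosin Myo18b 19 and 19, the centrosomal protein Pcnt 18 and 19, and Dst 16 and 15. Larger differences were seen in Hip1, with 6 wild-type and 11 knockout sites. Rad50 had 6 and 10, Cep290 5 and 9, and Golgb1 10 and 6.

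Genes in one list only were mostly weak. The percent of sites without an overlapping site fell at each 10% step of score and reached 2.40% and 1.64% in the strongest 10% of the wild-type and knockout lists. That fall is what a calling threshold predicts. Most of the 933 and 772 genes in one list only may thus have sites that passed in one library and missed in the other. How near they came is unknown, since a list holds no value for a site it lacks. A peak outside the other mRNA list is also open. Of 768 knockout-only genes between flanking wild-type sites, only 9 had no missing wild-type site number. For wild-type-only genes in the knockout list it was 7 of 920. Small changes in methylation or RNA abundance between the genotypes would also show first at weak sites, and with 1 library per genotype and no depth they stay open, untested.

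There were 51 genes whose site in one list only was in the strongest 25% of its list. Of them, 11.8% (4.44 to 23.9) had a site of the other list within 2 kb. For most of them this argues against another symbol within the other list as the cause. The search covered listed sites only, so it could not see a site assigned to a transcript outside the mRNA list. Gene assignment may account for 4 of the 6 that had a site of the other list within 2 kb, by an overlapping site or the same gene ID (March2, Eef2kmt, Gm1078 and Sbk3), and stays open for Arl6ip4 and Ogfod2, whose sites lay 1195 bp apart. The other 45 genes, including Tpm1, Hnrnpk, Uqcrh, Kitl, Notch3 and Atg4a, had no site of the other list within 2 kb. Whether the other library had a peak that is not among its mRNA sites cannot be told apart from a true absence for most of these, since of the 45 only 2, Cxx1a and Ufsp1 (folds 5.32 and 17.7 in the knockout list), had no missing site number in the wild-type list. A genotype effect stays open and untested, and for Cxx1a reads could also be shared with its near-identical neighbour Cxx1b, which had a wild-type site with a fold of 5.38.

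The knockout-only site at the 5′ end of Abraxas2 was weighed against chance at the threshold. Of 1294 knockout sites with a score within 20% of its own, 30.8% (28.3 to 33.4) had no overlapping wild-type site, so a miss in the wild-type list is common at this strength and threshold calling may account for it. A candidate explanation from the design is that RNA of the 5′ end remains in the knockout; the list held 1 site inside the span, but this cannot be told apart from the threshold, since the position of the deletion and the input coverage were not used here. Between the flanking wild-type sites, 96.9 kb apart, 6 site numbers were missing, so a wild-type peak outside the mRNA list is also open.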
